A study of Homo sapiens with 8 samples.

How the data were processed

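HL-60 cells, an established human promyelocytic leukaemia line, were treated with decitabine or with its vehicle DMSO, and N6-methyladenosine (m6A) in RNA was measured by methylated RNA immunoprecipitation sequencing (MeRIP-seq). Per the labels' protocols, cells received decitabine to 100 nM on 3 occasions (0 hours, 24 hours and 48 hours), RNA was taken at 72 hours, and 2 µg of fragmented RNA was immunoprecipitated with 5 µg of an anti-m6A antibody. Input and immunoprecipitated libraries were read as single 50-base reads, per the labels' protocols. The 8 libraries form 4 groups of 2 (m6A and input, each with decitabine and DMSO), grouped by their titles.

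STAR 2.7.3a and the genome build hg38 are named in the submitters' processing notes. The tool that scored the features, its correction for input and for library size, and the rule by which the libraries were combined are not given in the sources used here. The authors' deposited table of their own comparison was the only data used: it lists features with a position, strand, gene name, Ensembl identifier, log ratio and p-value. It holds no value per library, so the depth of each library is unknown here, no error or replicate spread can be attached to any ratio, and no leave-one-out or paired fit was made. The deposited log ratio carries no base in its header. It was read as a natural log, because its exponential was a multiple of 0.5 to a relative tolerance of 1e-08 for 1415 of the 4626 features, against 0 features when the base was taken as 2. The deposited p-value is not marked as adjusted. The authors' deposited table held no feature with an absolute natural log ratio under 0.5 and none with a p-value above 0.00455, so it is a list of features that had already passed a threshold. The number of features tested is unknown here, so no false discovery rate was computed over all tests, and no enrichment of a gene list in the table was tested. Which arm is the numerator is not stated. The table is named for decitabine and DMSO is the vehicle control, so a positive value is likely decitabine over DMSO. The text calls features positive or negative and gives the ratio of the larger to the smaller arm as a fold.

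Of the features in the authors' deposited table, 4511 covered 50 nt, the widest covered 150 nt, and 194 were written as several blocks. In all of the latter the last block ended 1 base past the written end unless both ends were counted in, so positions were read as 1-based with both ends included, on hg38. Gene spans came from a RefSeq table of GRCh38.p14, the same primary assembly. Of the 3114 gene names, 2867 matched a symbol on the same chromosome, 58 a synonym and 189 none, and 4312 features (93.2%) lay inside the span of the matched gene. Exons, introns and UTRs were not annotated here, and no sequence motif was searched, since no genome sequence was used. The 10 features on chromosome Y were copies of chromosome X features with the same values (the pseudoautosomal regions). They stay in the totals and were left out of all tests by gene, chromosome and position.

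Before the data were examined, 16 gene lists, the planned tests, the processing alternatives and the rule for named genes were fixed. That rule represents each gene by its leading feature (the smallest p-value) and takes the 12 largest positive and 12 largest negative ratios, up to 4 members of each list by p-value, and 11 genes of prior interest in any case. Some genes that the rule would name are not reported here. The lists were m6A machinery, mRNA decapping and decay, DNA methylation and decitabine metabolism, DNA damage and p53 response, apoptosis, interferon and double-stranded RNA response, cancer-testis and germline genes, myeloid identity, leukaemia genes with known m6A targets, cell cycle, chromatin regulators, splicing factors, ZNF-named zinc finger genes, histone genes, ribosomal proteins, and markers of lymphoid and erythroid cells. Planned count-based fits and tests of passing against failing features could not be run on a table of passing features alone. In place of the latter, each list with 5 or more genes in the table was compared with all other genes in the table, by the share of genes with a positive ratio (two-sided Fisher's exact test, chosen after the table was seen) and, as planned, by the two-sided percentile of its median log ratio among 10000 random lists of the same size, matched on features per gene (4 or more as a single class). P-values were adjusted by Benjamini-Hochberg over the 12 lists with enough genes. They treat genes as units within this single comparison and say nothing of the spread between cultures. Agreement of sign within genes was compared with 10000 permutations of the signs over all features, and positions by 100000 permutations. Intervals on shares are 95% Wilson intervals and cover counting of features only. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

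The sign test of gene lists, the test of sign agreement and the search for multiples of 0.5 were run on simulated data. The tests of medians, of genes with both signs and of positions were not simulated. For lists of 16 genes with a planted positive share of 80%, the sign test was called in 39% of runs, for lists of 40 genes in 78%, and for lists of 8 genes in 14%, over 3114 genes. A call was an unadjusted Fisher's exact p under 0.05, which is looser than the correction over lists, and no negative shift was planted. The test of sign agreement between neighbouring features was called in 97% of runs at a planted sign correlation of 0.1 within genes, over 4616 features. Alternatives were a limit on the size of the change, a single feature per gene, other summaries per gene, other limits on p, and the table without the ratios that are multiples of 0.5 or without ratios of 8-fold and more.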

Results

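m6A was compared between HL-60 cells treated with decitabine, a deoxycytidine analogue that traps and depletes DNA methyltransferases, and HL-60 cells given DMSO. The comparison asks where in the transcriptome the m6A signal differed after 72 hours of treatment. The design holds 2 cultures per treatment, each with an m6A immunoprecipitate and an input library, and the labels describe the cultures only as duplicates. The authors' deposited table of that comparison lists 4626 features under 3114 gene names, and all of the values here come from it. Each ratio is a single value over the libraries of both arms, with no error and no replicate value, and the depth behind it is unknown. Its correction for input is also unknown, so a ratio may partly reflect a difference in RNA level. A positive ratio is likely decitabine over DMSO, but the orientation is not stated.

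Features of both signs were listed in large numbers, and large ratios were more numerous on the positive side. The table held 2604 positive and 2022 negative features, so 56.3% were positive (95% Wilson interval 54.9 to 57.7). The median positive feature had a ratio of 10.1-fold (quartiles 3.04 and 98.6), and the median negative feature 3.95-fold (quartiles 2.46 and 9.24). Ratios of 10-fold or more made up 50.1% of the positive features (1305) and 23.5% of the negative ones (476). The positive ratios had a gap in the middle, with 702 features between 2-fold and 4-fold, 108 between 8-fold and 16-fold, and 236 between 32-fold and 64-fold. Among the negative features the corresponding counts were 777, 196 and 90.

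Most of the extreme ratios were multiples of 0.5 to a relative tolerance of 1e-08, and are called stepped ratios here. Whole-number totals give such ratios when the smaller arm is at the lowest counts, so their size may reflect a nearly empty arm. Stepped ratios made up 44.2% of the positive features (1151) and 13.1% of the negative features (264). They were 87.0% of the 1561 features of 20-fold or more and 0.815% of the 2700 features under 8-fold. Without them, 1453 positive and 1758 negative features remained, a positive share of 45.3%, with median ratios of 3.33-fold and 3.52-fold. This remainder still held large ratios that are other simple fractions, among them 226.333-fold in SAMD9, 127.333-fold in ZNF704 and 24.3333-fold in MKI67. It is therefore not free of ratios of that kind.

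**Figure D1:**
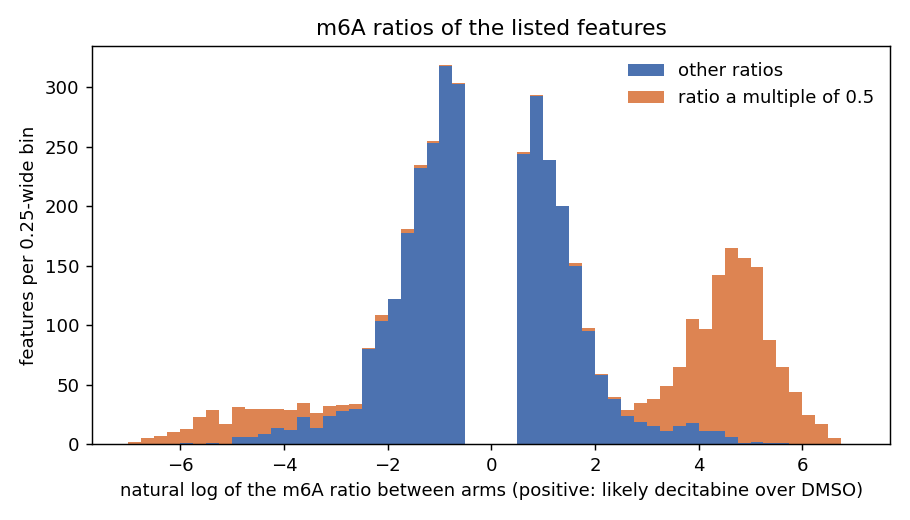
Histogram of the natural log of the m6A ratio for the listed features, with ratios that are multiples of 0.5 stacked on the others; 1 feature at 20.81 lies outside the axis. No feature lies within 0.5 of 0, both signs have a peak at small ratios, and the positive side has a further peak made almost wholly of the 1151 stepped ratios.

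Each gene was represented by its leading feature, the one with the smallest p-value, and the 12 largest ratios of each sign are named. In the authors' deposited table, CREBBP, a histone acetyltransferase, had a 735-fold feature (ENSG00000005339.15, hg38 chromosome 16, 3728699 to 3728748, minus strand, p = 1.8e-10), which lay 3670 nt from the 3' end of the gene span. In the authors' deposited table, NSD1, a histone H3 lysine methyltransferase, had a 629-fold feature (chromosome 5, 177210091 to 177210140, p = 3.6e-08), and CDK12, a kinase of RNA polymerase II, a 692-fold feature (chromosome 17, 39462836 to 39462885, p = 8.0e-09). The authors' deposited table gave PRDM2, a zinc finger protein with a methyltransferase domain, 763-fold (p = 2.3e-09), MLLT10, a fusion partner gene in leukaemia, 614-fold (p = 2.9e-08), and UBN2, a subunit of a histone chaperone complex, 629-fold (p = 1.0e-09). MIER3 stood at 670-fold, HACD3 at 662-fold, MEGF9 at 592-fold, the clone-named gene AC138932.1 at 631-fold and the readthrough gene ANKHD1-EIF4EBP3 at 851-fold in the authors' deposited table. Reads of the last of these can also belong to its parent gene ANKHD1. All 11 of these ratios were stepped. Other features of some of these genes had the opposite sign in the authors' deposited table, among them negative features of 8.30-fold in CDK12, 6.91-fold in PRDM2, 16.02-fold in CREBBP, 5.52-fold in NSD1 and 2.56-fold in MEGF9. UBN2 and ANKHD1-EIF4EBP3 also held negative features, of 2.13-fold and 2.39-fold, in the authors' deposited table. The single larger value, 20.81 on the natural log scale for the antisense RNA L3MBTL2-AS1, lay far outside the rest of the authors' deposited table and was not read as a fold.

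Among the 12 largest negative ratios, the authors' deposited table listed ZNF574 and ZNF93, zinc finger genes on chromosome 19, at 894-fold (42079914 to 42079963, p = 0.00016) and 887-fold (19933627 to 19933676, p = 1.4e-05). RREB1, a zinc finger transcription factor, was at 618-fold in the authors' deposited table (chromosome 6, 7247101 to 7247150, p = 4.6e-05), 4855 nt from the 3' end of its span. In the authors' deposited table UBXN4 stood at 545-fold, DYNLL2, a dynein light chain, at 465-fold, EEF1AKNMT, which methylates the elongation factor eEF1A, at 513-fold, ARMH1 at 587-fold, and MYO1G, a myosin of blood cells, at 498-fold (p = 3.5e-07). LRRC37A3 (545-fold) and the pseudogene LRRC37A17P (526-fold) in the authors' deposited table belong to a family of related copies, between which the assignment of reads was not tested here. The antisense RNA SVIL-AS1 (615-fold) and the clone-named AC060766.7 (687-fold) were the others in the authors' deposited table. All 12 were stepped ratios. SVIL-AS1 also held a positive 138-fold stepped ratio, and RREB1 a positive 1.90-fold feature beside further negative ones, in the authors' deposited table.

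The genes of the m6A machinery carried features of both signs. Of the 29 symbols in the list, 12 genes were in the table, 7 with a positive and 5 with a negative leading feature, against 58.9% positive among the other genes (two-sided Fisher's exact test over genes, p = 1, Benjamini-Hochberg adjusted p = 1). With stepped ratios removed, 3 genes were positive and 5 negative, against 45.4% positive among the other genes (Fisher's exact p = 0.74). In the authors' deposited table the catalytic subunit METTL3 had a positive 10.1-fold feature (chromosome 14, 21503251 to 21503300, p = 0.00067) and its partner METTL14 a positive 159-fold stepped ratio (p = 0.0013). The authors' deposited table gave WTAP, the writer's adaptor subunit, a negative 1.78-fold feature (p = 0.00074) and the demethylase ALKBH5 a negative 52-fold stepped ratio (p = 0.0032). RBMX (291-fold), RBM15B (220-fold) and YTHDF2 (59-fold), an m6A reader, led the list by p-value in the authors' deposited table, all 3 positive and stepped. YTHDF2 also held a positive 2.75-fold and a negative 2.23-fold feature within its span in the authors' deposited table. FTO, DNMT1, DNMT3A, DNMT3B and DCK, also fixed in advance, were not among the listed features.

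The lists closest to the action of decitabine held genes of both signs, and none differed from the other genes past the threshold. Of the 9 listed genes of DNA methylation and decitabine metabolism, 4 were positive and 5 negative (Fisher's exact p = 0.50, adjusted p = 0.67). The authors' deposited table placed TET3, a 5-methylcytosine dioxygenase, at a negative 4.51-fold (p = 6.5e-05), with further features at a positive 4.31-fold and a negative 2.08-fold, and its relative TET1 at a positive 4.20-fold (p = 0.00020). UHRF1, which brings DNMT1 to replicating DNA, had positive features of 2.80-fold and 5.68-fold in the authors' deposited table, and the methyl-CpG binding protein MBD1 a negative feature of 2.93-fold. Of 8 DNA damage and p53 response genes, 3 were positive and 5 negative (adjusted p = 0.57, Fisher's exact test). TP53BP1 was at a negative 12.2-fold (p = 1.5e-05), GADD45A at a positive 3.32-fold, BRCA2 at a negative 3.27-fold and RNF4, a SUMO-targeted ubiquitin ligase, at a negative 2.84-fold in the authors' deposited table. Of 5 apoptosis genes, 1 was positive and 4 negative (adjusted p = 0.50, Fisher's exact test). The apoptosis inhibitor BIRC2 had a positive 109-fold stepped ratio in the authors' deposited table, where CASP8 was at a negative 3.08-fold and 2.13-fold, BCL2L1 at a negative 3.34-fold, and MCL1 at a negative 1.84-fold and positive 5.53-fold and 3.10-fold. BCL2 carried a negative 5.05-fold feature 4312 nt from its 3' end (chromosome 18, 63127633 to 63127682, p = 0.0014) and a positive 4.69-fold feature near its 5' end (63318783 to 63318832, p = 0.0030) in the authors' deposited table.

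Interferon, myeloid and leukaemia genes were also mixed. Of 7 interferon and double-stranded RNA response genes, 3 were positive and 4 negative (adjusted p = 0.67, Fisher's exact test). SAMD9L had positive stepped ratios of 230-fold and 107-fold, its neighbour SAMD9 negative features of 226-fold and 2.58-fold and a positive 2.28-fold feature, the RNA-editing enzyme ADAR a negative 3.46-fold feature and XAF1 a negative 22.5-fold stepped ratio in the authors' deposited table. Of 11 myeloid identity genes, 5 were positive and 6 negative (adjusted p = 0.64, Fisher's exact test). In the authors' deposited table CSF2RB, the shared beta subunit of the GM-CSF receptor, was led by a positive 51.5-fold stepped ratio, the G-CSF receptor CSF3R by a negative 17.5-fold, GFI1 by a positive 1.97-fold and the formyl peptide receptor FPR2 by a negative 9.80-fold feature. CSF2RB also held a positive 4.73-fold and a negative 18.4-fold feature in the authors' deposited table. Of 15 leukaemia genes, 8 were positive and 7 negative (adjusted p = 0.95, Fisher's exact test). WT1 was at a positive 211-fold stepped ratio (p = 4.9e-08), KMT2A was led by a negative 3.71-fold and LMO2 by a positive 3.69-fold feature in the authors' deposited table. The other features of KMT2A were positive in the authors' deposited table, at 201-fold and 123-fold (both stepped) and 2.14-fold. Both listed features of MYC were negative, at 3.79-fold (chromosome 8, 127737627 to 127737676, p = 0.0022) and 5.04-fold (127738586 to 127738635, p = 0.0035) in the authors' deposited table. Of the cancer-testis and germline list, 1 gene, PRAME, was listed, with negative features of 2.26-fold and 1.73-fold in the authors' deposited table.

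Most splicing factors had a negative leading feature, a difference that did not pass the correction over the 12 lists. Of 16 splicing factors, 4 were positive and 12 negative (Fisher's exact p = 0.0088, adjusted p = 0.11), and their median log ratio lay at percentile 2.57 of random lists (adjusted p = 0.17). Without stepped ratios the counts were also 4 and 12, against 45.5% positive among the other genes (Fisher's exact p = 0.13). SON, a splicing cofactor, had 5 negative features between 1.87-fold and 10.4-fold in the authors' deposited table, and SRSF8 was led by a negative 8.61-fold, the SR-related SRRM2 by a negative 2.07-fold and the SR-protein kinase CLK2 by a negative 2.49-fold feature. SRSF8 also held a positive 5.12-fold feature in the authors' deposited table. Of 8 cell cycle genes, 2 were positive and 6 negative (Fisher's exact p = 0.071, adjusted p = 0.29). With stepped ratios removed, 2 cell cycle genes were positive and 4 negative, against 45.4% positive among the other genes (Fisher's exact p = 0.70). MKI67, a proliferation marker, was led by a negative 11.5-fold, CDK2 by a negative 227-fold stepped ratio, E2F3 by a negative 3.11-fold and CENPF, a kinetochore protein, by a negative 5.87-fold feature in the authors' deposited table. MKI67 also held positive features of 24.3-fold and 1.89-fold, and CENPF a positive 4.35-fold feature, beside further negative ones in the authors' deposited table. Of 8 mRNA decapping and decay genes, 3 were positive and 5 negative (Fisher's exact p = 0.29, adjusted p = 0.57). The nonsense-mediated decay factors SMG5 and UPF1 were at a negative 14.7-fold and 10.2-fold, and SMG1 and the deadenylase subunit CNOT4 were led by positive 2.07-fold and 2.41-fold features in the authors' deposited table. CNOT4 also held a negative 63.5-fold stepped ratio in the authors' deposited table.

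Chromatin regulators and zinc finger genes supplied the longest lists. Of 41 chromatin regulators, 24 were positive and 17 negative, the share of the other genes (58.5% against 58.9%, Fisher's exact p = 1). With stepped ratios removed, 15 chromatin regulators were positive and 20 negative (42.9% against 45.4%, Fisher's exact p = 0.86). EP300 (176.5-fold), CREBBP, CHD7 (375-fold) and NSD1 led by p-value in the authors' deposited table, all positive and stepped, and CHD7 also held negative features of 1.68-fold and 1.71-fold. Of 248 ZNF-named genes, 163 were positive and 85 negative, 65.7% against 58.3% among the other genes (Fisher's exact p = 0.022, adjusted p = 0.13), and their median lay at percentile 99.6 of random lists (adjusted p = 0.091). Without stepped ratios the positive share of ZNF-named genes was 48.4%, against 45.1% of the other genes (Fisher's exact p = 0.40). The ZNF-named genes held 9.51% of the listed features, 250 of them on chromosome 19, and how reads shared between related genes were assigned is not given in the sources used here. Among these ZNF429 had the smallest p-value in the authors' deposited table (positive 426-fold, chromosome 19, 21537061 to 21537159, p = 1.1e-15). Of the remaining lists, 3 genes with ribosomal protein symbols were listed, with RPL22 at a negative 2.00-fold, RPL28 at a negative 2.82-fold and RPL7L1 at a positive 2.69-fold in the authors' deposited table. The linker histone gene H1-10 was at a positive 2.46-fold in the authors' deposited table, and of the lymphoid and erythroid markers 0 were listed. By the largest change per gene in place of the leading feature, 2 decay genes were positive and 6 negative (Fisher's exact p = 0.069, adjusted p = 0.28), and 3 cell cycle genes were positive and 5 negative (Fisher's exact p = 0.28, adjusted p = 0.67). In that setting apoptosis had 2 positive and 3 negative genes (Fisher's exact p = 0.40, adjusted p = 0.67), chromatin regulators 26 and 15 (p = 0.63, adjusted p = 0.76) and ZNF-named genes 162 and 86 (p = 0.051, adjusted p = 0.28), and the counts of the other tested lists did not change. Over all 12 tested lists, 0 passed the correction in either test, and 2 had an unadjusted p under 0.05 by sign and 1 by median. Genes are not independent replicates. In simulation a planted positive share of 80% was called, without correction over lists, in 14% of runs for lists of 8 genes. For lists of 40 and 200 genes it was called in 78% and 100% of runs, and no negative shift was simulated.

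**Figure D2:**
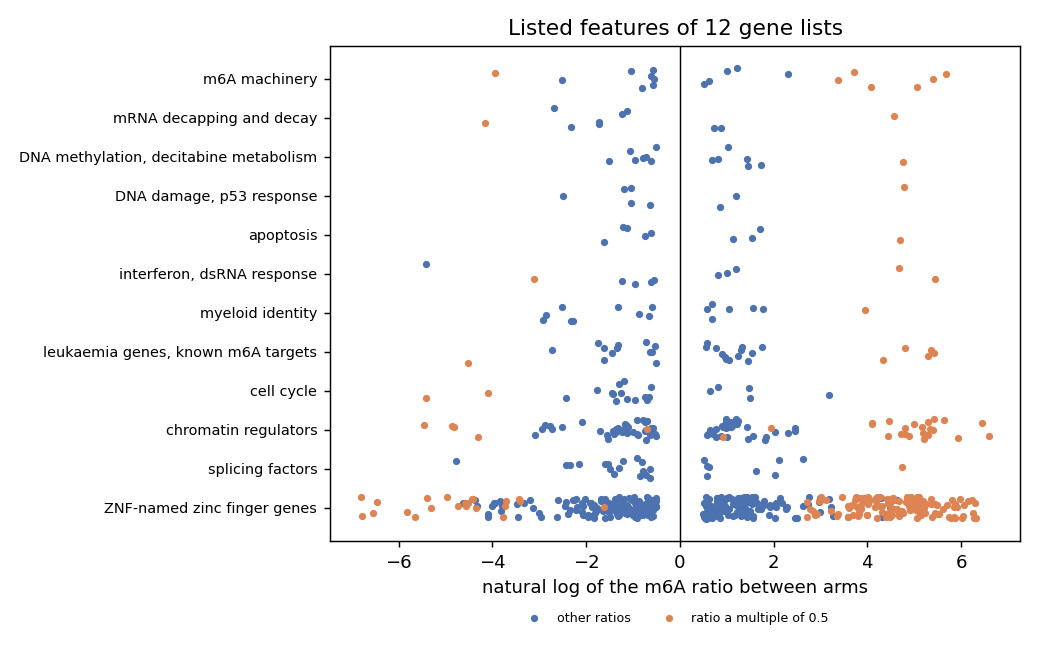
Natural log of the m6A ratio of each listed feature in the 12 tested gene lists, with vertical jitter and with ratios that are multiples of 0.5 in orange. Every list holds features of both signs, and 158 of the 439 features of ZNF-named genes and 28 of the 97 features of chromatin regulators are stepped.

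Several listed features of a gene often differed in sign. Of 946 genes with more than 1 feature, 552 (58.4%) had both positive and negative features, 253 had only positive and 141 only negative ones. Permuting the signs over all features gave 60.1% with both signs (central 95% range 57.2 to 63.1, two-sided permutation p = 0.25). Neighbouring features of a gene had the same sign in 801 of 1502 pairs (53.3%), against 50.8% in permutations (48.3 to 53.3, permutation p = 0.048), and in 52.5% of 901 pairs without stepped ratios (permutation p = 0.23). Pairs at most 500 nt apart agreed in 53.4% of 663 cases (permutation p = 0.19), pairs from 500 to 5000 nt apart in 55.3% of 537 cases, past the permuted range of 46.6 to 54.9 (permutation p = 0.038, not adjusted), and pairs over 5000 nt apart in 49.7% of 302 cases (permutation p = 0.75). Of the 104 pairs with about 1 bin between them, 51 had the same sign. Bins that touch were always joined in the table, so their agreement is not visible.

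**Figure D3:**
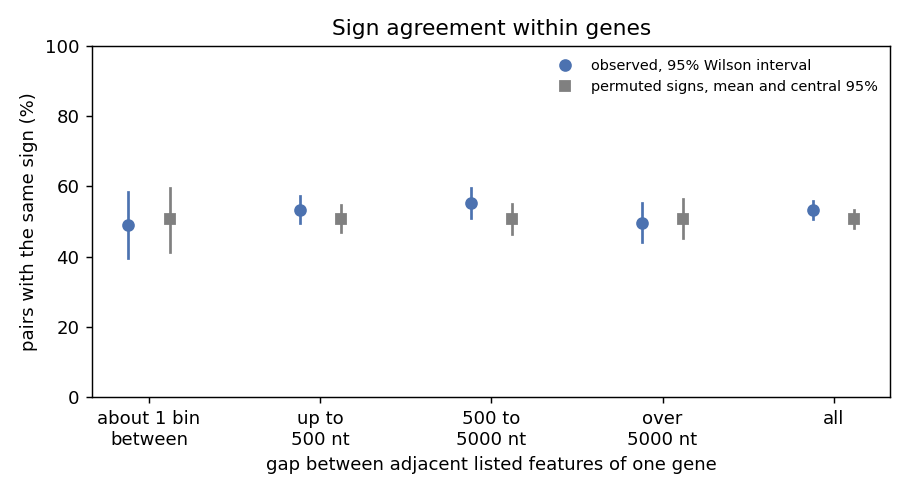
Share of neighbouring listed features of a gene that have the same sign, by the gap between them, with 95% Wilson intervals (blue), beside the mean and central 95% range of 10000 sign permutations (grey). The observed shares lie between 49.0% and 55.3% in all gap classes, and the share of pairs from 500 to 5000 nt apart (55.3%) lies above its permuted range.

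Most features lay in the part of the gene span nearest the 3' end, and no difference in position between positive and negative features was detected. The median feature lay at 81.7% of the gene span from the 5' end for positive and 82.2% for negative features, a difference of -0.56 percentage points (permutation p = 0.64). The median distance to the 3' end of the span was 4048 nt for positive and 4150 nt for negative features (permutation p = 0.65). The part of the span from 75% on held 57.2% of positive and 57.9% of negative features. Of the 4626 features, 4511 covered 50 nt, and 194 were written as several blocks with a gap between them. Gene spans include introns, so these positions are not distances along the mRNA.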

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

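The p limits of 0.001 and 0.0001, the removal of stepped ratios (multiples of 0.5) and the limit at 8-fold were chosen after seeing the data. The positive count of 2604 became 1472 at p under 0.001, 758 at p under 0.0001, 1453 without stepped ratios and 1251 under 8-fold. The negative count of 2022 became 959, 220, 1758 and 1449 under the same settings, and 1281 with a single feature per gene. The positive share of 56.3% became 58.9% with a single feature per gene, 61.1% in the features with the smaller p-values, and 60.6% at p under 0.001, and it turned to 45.3% without stepped ratios and 46.3% under 8-fold. The median natural log ratio of 0.78 became 0.93, 1.13 and 1.08 in the same order and turned to -0.62 and -0.58. The turn follows at least in part from the construction, since stepped ratios were 81.3% positive and most large ratios were stepped. The planned adjusted p limits of 0.01 and 0.1 and an unadjusted limit of 0.05 removed no feature, since the table was already limited more strictly, so they test nothing. No gene list passed the correction by leading features, under the other summaries per gene or without stepped ratios, and the share of genes with both signs and the positions kept their side of the threshold. Other count-based tools, pseudocounts, low-count filters and leaving out replicates were not run without values per library, and the motif and central-base alternatives were not run without a genome sequence. No paired analysis was possible because the table has no column per library. Whole-number totals give a multiple of 0.5 when the smaller arm is at the lowest counts, so large stepped ratios may rest on a nearly empty arm. Depth is unknown, so which of them do cannot be resolved.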

Other observations

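The test of all other features of genes with stepped ratios, the test of a depth gap, the test of feature width and the joint rule on sign agreement were chosen after the result was seen, as were the tests of runs of features of a single sign and of lncRNAs and pseudogenes. A small set of genes carried runs of negative features with no stepped ratio among them. Of 126 genes with 4 or more features, 9 were negative and 14 positive throughout. Permuting signs separately within stepped and within other features gave a mean of 4.21 negative genes (central 95% range 1 to 8, permutation p = 0.044) and 8.81 positive genes (4 to 14, permutation p = 0.097), with neither p adjusted for the other. Permuting over all features, which ignores that stepped ratios are mostly positive, gave means of 3.33 (permutation p = 0.011) and 9.69 (permutation p = 0.21). The 9 genes in the authors' deposited table, chosen after their values were seen, included PLEC, a cytoskeletal linker (7 features, median 4.42-fold), SON (5 features, 4.41-fold), BAHCC1, ARHGAP35, EMILIN2, POGZ, TRIOBP and TSHZ1. The 14 positive genes in the authors' deposited table, chosen likewise, included KMT2C, a histone methyltransferase (4 features, median 5.51-fold), CCP110, a centriolar protein (5 features, 3.46-fold), and CSNK1D, a casein kinase (5 features, 101-fold, of which 4 stepped). ZNF429, ZNF468, ZNF117 and ZNF37BP were also positive throughout, each with 3 stepped ratios.

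Features in lncRNAs and pseudogenes were positive more often than those in protein-coding genes (64.8% of 244 against 55.5% of 4068, Fisher's exact p = 0.0052, not adjusted). Their ratios were stepped in 47.5% against 28.8% (Fisher's exact p = 2.3e-09). Without stepped ratios the positive shares were 49.2% and 45.5% (Fisher's exact p = 0.42). By chromosome, the lowest positive share was 43.4% of 129 features on chromosome 22 (Fisher's exact p = 0.0029, adjusted over 23 chromosomes p = 0.068), and none passed the correction.

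The excess of positive over negative stepped ratios (1151 against 264) goes with the majority sign of the table, which is positive with stepped ratios and negative without them (45.3% positive). The other, non-stepped features of the 1034 genes with a positive stepped ratio were positive in 46.7% of 598 cases (Wilson interval 42.7 to 50.7), against 45.2% of all non-stepped features. With stepped ratios kept, 58.0% of 1018 pairings of a positive stepped feature with another feature of its gene had a positive partner (bootstrap over genes 53.7 to 62.1), against 56.7% with signs permuted within each class (53.4 to 60.1, permutation p = 0.46). Neither share lay above its permuted range (41.6 to 48.8 for the first). In genes with another listed feature, this argues against a large shift of the whole gene as the general cause. Genes with a single listed feature (2167 of 3114 gene names) could not contribute, and the first share leaves out stepped features. Single genes such as CSNK1D were positive throughout. Bins below the threshold are not listed, so a smaller shift across a gene cannot be judged. A gap in depth between the arms was not excluded, since the positive share of 81.6% among 772 stepped ratios of 100 or more (interval 78.7 to 84.2) only repeated the 81.3% among all stepped ratios. Few stepped features were over 50 nt wide (2.90%, against 2.28% of other features, Fisher's exact p = 0.22), so wider features cannot make up most of the excess. Whether a single listed bin belonged to a broader peak with unlisted bins cannot be judged. A gap in depth, uneven sampling of few molecules in the smaller arm, and a value set in for an empty arm by the scoring tool remain open. The same holds for m6A that differed between the arms at single sites (a biological explanation, untested, gained or lost with decitabine depending on the orientation). Because the correction for input is unknown, a difference in RNA level was not separated from one in m6A. Some stepped features of different genes shared both ratio and p-value (METTL14 and ZNF816-ZNF321P at 159-fold, SAMD9L and ZNF468 at 107-fold). ZNF225 had another p-value at 107-fold. No library values are at hand to separate these explanations.

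Features of a gene went both ways about as often as permuted signs would. The same-sign share of neighbouring pairs, 53.3%, lay just past the permuted range, but it did not without stepped ratios (52.5% of 901 pairs, permutation p = 0.23), and the count of genes with both signs lay inside its range, so independence of the signs from the gene is not settled. If neighbouring bins reported on a shared m6A peak, near pairs should agree more than far pairs. The difference was 3.72 percentage points (bootstrap interval -3.11 to 10.6, permutation p = 0.29), an interval too wide to decide. Bins that touch were joined in the table, so the closest bins are missing from the near pairs. A hypothesis consistent with these values is that much of the listed change is specific to single bins, whether by site-specific m6A or by sampling noise per bin, and values per library would be needed to tell which.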
